A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

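The series holds 22 calling-card libraries of Saccharomyces cerevisiae, in which insertions of the retrotransposon Ty5 were recovered by digestion with Hinp1I, HpaII or TaqI, self-ligation, inverse PCR and sequencing on an Illumina GAII. They are 1 library of a diploid without Sir4, 3 libraries of that strain with a Gal4, Leu3 or Gcn4 fusion to Sir4 on a plasmid, 16 multiplex libraries (8 barcoded fusions in 2 pools) and 2 libraries of a haploid with THI2 fused to sir4 at its own locus, in complete medium or starved of thiamine. The medium of each library (glucose or galactose) is not given in the sources used here. Per the labels and the series text, the deposited files list a chromosome, a position, a direction and the counts, which are the authors' raw numbers of sequencing reads at each insertion site, without normalization. The aligner, genome build, read filters and any merging of sites are not given in the sources used here.

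A count in every comparison is 1 distinct insertion site. The Sir4-free file lists 4019 sites more than once, up to 4 times, and each was counted once. The libraries held 444512 sites and 17876182 reads together, with 4755 to 79573 sites per library. The 2 sites with most reads in the Sir4-free library (chromosome 3, positions 1430 and 4323) lie where the strain carries its native Ty5 element and were listed in 20 libraries. They were kept as sites and their reads are given apart.

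The regions planned before the data were examined were promoter regions of the reference annotation. The annotation held here is of assembly R64 (strain S288C), and its displacement from the data was scanned in 150-kb segments in steps of 10 bp over a range of 600 bp. On chromosome 11 beyond the first segment it was displaced by 380 to 390 bp, and elsewhere 72 of 77 segments were within 60 bp (median 20 bp). The builds therefore differ, so 1-kb bins in the data's coordinates replaced promoter regions, and no annotation coordinate is printed. R64 served for names and neighbours and for the upstream windows of genes in the list tests. It also served to find the bins of HML and HMR and the stretches at deleted genes. These steps carry its displacement. A bin was named by genes whose 5′ end lies in it or within 500 bp (900 bp on chromosome 11), otherwise as near the closest gene.

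Single libraries were compared by a two-sided Fisher's exact test per bin with at least 5 sites in both libraries together. The plasmid, Thi2 and multiplex libraries were each set against the Sir4-free library, and the starved against the complete-medium Thi2 library. P values were adjusted by the Benjamini-Hochberg method within each comparison (threshold 0.05). The multiplex libraries were fitted together in edgeR 4.0.16 (limma 3.58.1, R 4.3.3; glmQLFit, glmQLFTest, TMM factors) over 5460 bins with at least 10 sites in the 16 libraries, each fusion against the mean of the other 7. The biological coefficient of variation was 0.0908 with 8 residual degrees of freedom. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Log2 folds of Fisher comparisons add 0.5 site to each count. Shares of single libraries carry 95% Clopper-Pearson intervals, ratios carry conditional exact intervals, and a count of 0 was set to 3 counts to give a ratio. Such a ratio leaves out the counting error of the other count, so it is not a lower confidence limit. Higher bins that touch were joined into loci.

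For the sharing of the pools, replicate numbers are the pool numbers. Across 252 bins with at least 160 multiplex sites, the log2 differences between replicates 1 and 2 of 1 fusion were correlated with those of another with a median of 0.0757 over 28 pairs (-0.0496 to 0.176, 11 above 0.1), so the replicate block was kept as an alternative.

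Bins are named by a rule written before the data were examined: in each single-library comparison and direction the 10 with the smallest p and then the 10 with the largest fold, with at least 5 sites, and for each multiplex fusion the 10 with the smallest p that were above the others in both replicates. The text prints a selection of these, members of the fixed lists that were called, and up to 3 uncalled members with most sites. Other genes were named for their function after their values were seen. The result of 1 gene is not reported here. The 13 lists (Gal4 targets, Leu3 targets, Gcn4 targets in amino acid synthesis, thiamine synthesis and uptake, multidrug resistance, mating and karyogamy, filamentous growth, cell wall, iron regulon, hexose transport, glycolysis, and ribosomal proteins and heat shock as control lists) held 278 entries. Of these 13 on chromosome 11 were left out and 1 was not matched. A gene was called when a bin within 600 bp upstream of it was higher. Lists were tested by a one-sided Fisher's exact test against all other tested genes (up to 5684) with adjustment over the lists of a library.

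The tests were tried on simulated data with 200 changed bins. Simulated counts varied by counting error alone, and all fusions had the same shares apart from the changed bins. Changed bins were drawn from those with at least 10 multiplex sites (edgeR) or at least 5 Sir4-free sites (Fisher). The rates found may therefore be better than in the real data. The edgeR comparison of Kar4 found 23.8%, 59.1% and 93.9% of bins changed 2-, 4- and 8-fold with 5 false calls. The Fisher comparison found 0%, 13.4% and 54.5% at the depth of the Leu3 library (0 false) and 0%, 32.8% and 89.4% at that of Gcn4 (3 false).

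Alternatives were: sites with at least 2 or 5 reads, sites within 3 bp merged, no minimum or 10 sites, the plasmid libraries as control, library totals without TMM, DESeq2 1.42.0, the replicate block, each replicate left out, the Sir4-free library as control in the same fit, a site found under several barcodes kept for the one with most reads, and 10 or 30 kb to a chromosome end. Added after the data were seen were bins shifted by 500 bp, each Sir4-free listing counted, leaving out the deepest multiplex library, leaving out each library's higher bins near chromosome ends, and thinning the complete-medium library (20 draws). Not run, for want of a genome sequence in the data's coordinates or an annotation of the same build, were motif enrichment, classes by coding sequence, promoter or tRNA gene, the list of essential genes, and the promoter-region alternatives.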

Results

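Calling cards record where a DNA-binding protein sat by the position at which the yeast retrotransposon Ty5 integrated. The transcription factor is fused to a piece of Sir4, the silencing protein that tethers Ty5 integrase, so that insertions gather near the bound DNA. The data address where such fusions send Ty5, whether 8 barcoded fusions can be profiled in 1 pool, and whether Thi2 targets differ between media. A count is 1 distinct insertion site, that is 1 chromosome, position and direction, whatever its number of reads. The 22 libraries held 4755 to 79573 sites each. Site shares are percentages of a library's sites in a 1-kb bin in the coordinates of the deposited data, whose genome build is not named, and genes name bins by neighbourhood in the R64 annotation. The Sir4-free, plasmid and Thi2 libraries had no replicates, so Fisher's exact tests (two-sided) compare those libraries and not conditions. The brackets after shares of single libraries are 95% Clopper-Pearson intervals, and like the limits set by counts of 0 they cover counting error only, since PCR reads are not independent molecules. Tests, thresholds and the rule for naming bins were fixed before the data were examined, except where stated.

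Without Sir4, Ty5 was spread thinly and its fullest bins held about 0.1% of the sites each. The Sir4-free diploid, whose SIR4 copies are both deleted, gave 79573 sites, with at least 1 in 10907 bins and a median of 4 per bin. Its fullest bins were the leftmost bin of chromosome 2 near YBL113C and the bin at YCR006C (chromosome 3, 123001 to 124000), with 94 sites each, or 0.118% (0.0955 to 0.145). The bins at YAR035C-A and at CWP2, the gene of a cell wall mannoprotein, held 92 sites each. PSA1, which makes GDP-mannose, had 78, GLN1 for glutamine synthetase 74 and the vacuolar gene VTC1, beside ALD5, 72. The 10 fullest bins held 1.03% of the sites together.

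Gal4, the activator of the galactose genes, sent Ty5 to every gene of its target list. In the plasmid library 182 of 13383 sites fell in the bin between GAL10 and GAL1, the divergent genes for the epimerase and galactokinase (chromosome 2, 278001 to 279000), a share of 1.36% (1.17 to 1.57) against 0.0214% in the Sir4-free library. That is 63.7-fold (38.7 to 112; adjusted p 2.58e-128). GAL2, the galactose permease, took 249 sites or 1.86% (1.64 to 2.10), 39.0-fold (27.6 to 56.4; adjusted p 1.12e-162). GAL7, the uridylyltransferase gene, took 145 sites against 25, a log2 fold of 5.08. The regulatory gene GAL80 rose least among the list, with 19 sites against 23 in the far deeper control and a log2 fold of 2.30. GCY1, PGM2, MTH1, PCL10, FUR4 and GAL3 also passed, so 11 of 11 list genes were called, as against 3.05% of the other genes (one-sided Fisher's exact test, adjusted p 4.20e-16 over the 13 lists tested in that library; 11 adjusted over the list alone). GAL1 and GAL10 share a bin and are not independent.

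The fullest Gal4 bin, however, lay at GTO3, which encodes an omega-class glutathione transferase (chromosome 13, 773001 to 774000), and not at a GAL gene. It held 373 plasmid sites, 2.79% (2.51 to 3.08), 92.4-fold over the control (61.1 to 146; adjusted p 3.40e-276). Near PIH1 and NEL1 on chromosome 8 there were 175 sites against 4, and at SRB2, a subunit gene of the Mediator, 137 against 6, which is 136-fold (60.8 to 376). The divergent pairs SRP40/PTR2 with 221 sites, WHI5/LPX1 with 179 and RUP1/SFL1 with 160, and the G1 cyclin gene CLN3 with 182, completed the strongest bins together with the one at SNA2 and RBA50, with 198. YPR1, an aldo-keto reductase gene, had 50 sites against 0, 99.1-fold more with the 0 set to 3 counts, and YPS1 had 38 against 1 (226-fold, 38.2 to 9156). In all, 149 of 5577 bins at 106 loci were higher and held 58.7% of the Gal4 sites against 4.75% of the control's. A further 10 bins were lower, among them TEC1 and the cyclin gene PCL2 with 0 sites against 64 and 62, where a count of 0 allows a share of up to 0.0224%. A bin with few control sites could hardly be called lower at this depth. Sites in the higher bins also reduce the share of all other bins, so a lower call need not mean avoidance. The same limits hold for Leu3 and Gcn4 below.

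Leu3, the regulator of branched-chain amino acid synthesis, marked its own pathway and a set of genes outside it. LEU1, isopropylmalate isomerase (chromosome 7, 478001 to 479000), took 127 of 10662 sites, 1.19% (0.994 to 1.42), 47.4-fold over the Sir4-free share (29.4 to 80.2; adjusted p 3.08e-92). ILV5, beside ATG33, took 105 sites, 18.7-fold (12.9 to 27.4; adjusted p 1.33e-60), and OAC1, the mitochondrial oxaloacetate carrier, 63 sites, 22.4-fold. Of the Leu3 target list 9 of 10 tested genes were called, as against 2.52% of other genes (adjusted p 7.48e-13; 9 adjusted over the list alone). LEU4, LEU9, ILV2, ILV3, BAP2, BAT1 and GDH1 were among them, and ILV6 was the exception with 0 sites against 7. OAC1 was outside the list test because it lies on chromosome 11, where the annotation is displaced.

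The fullest Leu3 bin was near CSS1 on chromosome 9 (24001 to 25000) with 192 sites against 3, a share of 1.80% (1.56 to 2.07) and a ratio of 478 (161 to 2337). The bin of QCR6, a respiratory subunit, and PHO4, the phosphate regulator, held 173 sites, 27.5-fold. The iron regulator AFT1 with 98 sites, the nitrogen regulator GAT1 (beside FRS2) with 102, the dicarboxylate carrier DIC1 (beside ORM2) with 113 and VTC1/ALD5 with 104 followed. In all 106 of 5623 bins at 90 loci were higher, with 35.0% of the Leu3 sites against 3.53% in the control, and 2 were lower, PCL2 and the leftmost bin of chromosome 2.

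Gcn4, the general activator of amino acid synthesis, sent Ty5 to genes of amino acid synthesis. ARG3, ornithine carbamoyltransferase (chromosome 10, 268001 to 269000), took 250 of 23833 sites, 1.05% (0.924 to 1.19), 36.3-fold over the control (23.6 to 58.3; adjusted p 4.28e-126). ARG5,6, which appears as ARG56 in the annotation, had 135 sites (16.1-fold), ARG4 92 (27.9-fold) and ARG1 92 (21.9-fold). The vitamin B6 pair SNO1/SNZ1 had 103 sites, 15.0-fold, and ILV5 140, 11.1-fold. Of the Gcn4 list 31 of 46 genes were called, HIS4, ASN1, HIS5, LEU4 and ICY2 among them, as against 2.53% of other genes (adjusted p 4.44e-36; 34 adjusted over the list alone). The uncalled members with most sites were the permease gene AGP1 with 24 against 40, ARO3 with 16 against 24 and LYS2 with 11 against 20. THR1 had 0 sites against 10 (adjusted p 0.861).

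Outside its list, Gcn4 marked VHR1, a biotin-response regulator, with 102 sites against 6 (56.8-fold, 25.2 to 158), SPO24 with 161 (8.81-fold) and the sulfite pump SSU1 with 103 (16.4-fold). The bin of the stress gene DDR48 and PAI3 had 55 sites against 1, a ratio of 184 (31.6 to 7383). ARG2, beside PSF2, had 5 against 0, 5.56-fold more with the 0 set to 3 counts. The Leu3 list was also raised in the Gcn4 library, with 7 of 10 genes called (adjusted p 1.82e-08; 9 adjusted over the list alone): LEU1, LEU4, LEU9, ILV2, ILV5, ILV6 and BAT1, of which LEU4, ILV2, ILV6 and BAT1 stand in both lists. ILV6 had 12 against 3 for Gcn4, in another bin than the one with 0 against 7 for Leu3. The fusions were not tested against each other. In all 136 of 6136 bins at 117 loci were higher (22.4% of sites against 3.86%) and 15 were lower, among them the pyruvate kinase gene CDC19 with 2 sites against 50 and RPL26A with 0 against 30.

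**Figure D1:**
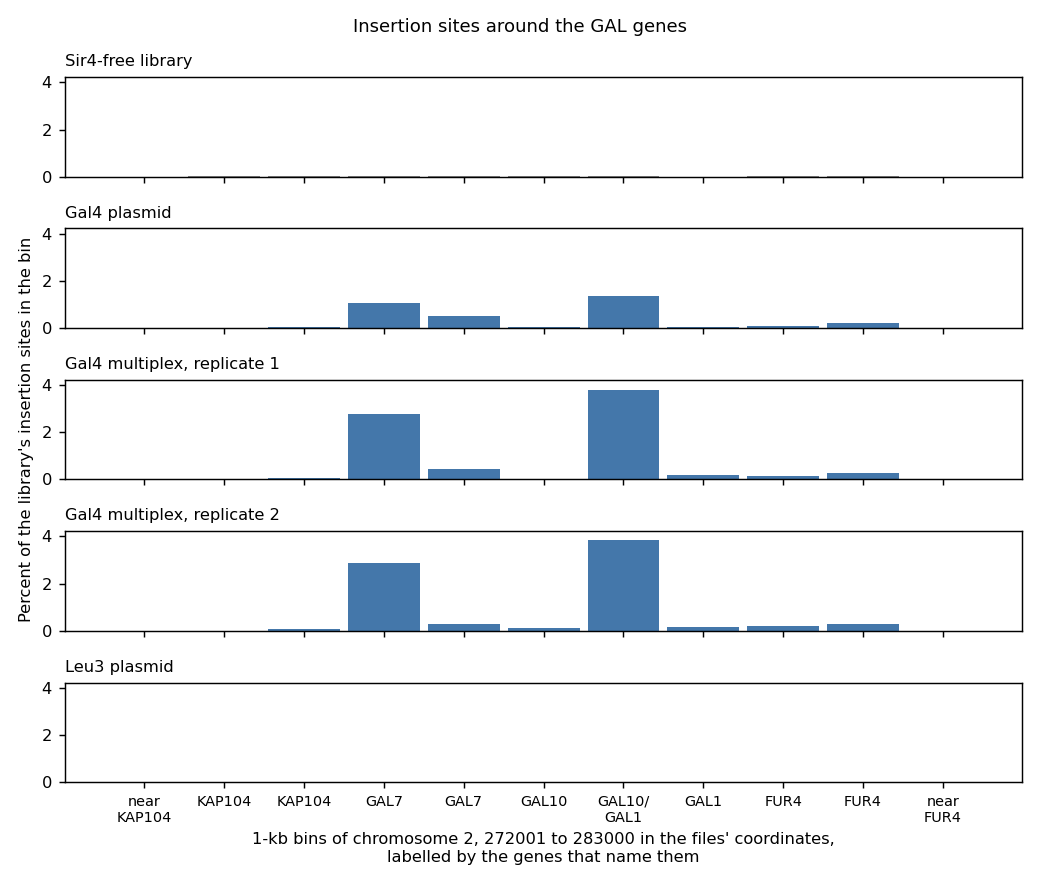
Percent of each library's insertion sites (vertical axis) in 1-kb bins of chromosome 2 from 272001 to 283000 (horizontal axis), with Gal4 libraries in blue and the Sir4-free and Leu3 libraries in grey. The bin of GAL10 and GAL1 held 1.36% of the Gal4 plasmid sites and a mean of 3.81% in the 2 multiplex replicates, against 0.0214% in the Sir4-free library.

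Gal4 profiled alone and Gal4 profiled in a pool of 8 fusions marked largely the same bins. Of 5315 bins tested in all 3 libraries, 148 were higher in the plasmid library and 123 in both multiplex libraries, and 114 were in both sets where independent sets would share 3.43 (Fisher's exact test, p 7.14e-192). GTO3 led both, with 772 and 669 sites in the multiplex replicates, a mean share of 4.80% ± 0.0195 (SD, n = 2). The GAL10/GAL1 bin held 3.81% ± 0.0333, GAL2 3.23% ± 0.0892 and GAL7 2.81% ± 0.0735. All 11 list genes were again called (edgeR; list adjusted p 9.97e-15; 11 adjusted over the list alone), with MTH1 the weakest at 10 and 3 sites (log2 2.40; adjusted p against the Sir4-free library in the same fit 0.109). Both sets were called against the same Sir4-free library, a single control that could not be split, so independence is not the value without targeting. Of libraries drawn at random from it, 0 called a bin in 20 draws. These draws took the control's shares as exact and were tested against that same control. They therefore cannot give the overlap that its counting error would create.

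The 16 multiplex libraries, 8 fusions in 2 pools that the series design describes as biological replicates, were compared in 1 edgeR fit. Each fusion was set against the mean of the other 7 over 5460 bins. The SDs below are between the 2 replicates and the log2 folds carry the standard error of the fit. These folds follow TMM scaling and set a fusion against the mean log level of the other 7. They therefore need not equal the ratio of the printed shares. The TMM factors ran from 0.665 to 1.74, with 1.74 and 1.66 for the replicates of Rgm1. Replicates of 1 fusion differed little beyond counting error. Between them 1 bin was called for Gal4 and 0 for each other fusion by Fisher's exact test, where 19 to 161 bins had an unadjusted p below 0.05, and the chi-square per bin was 0.995 to 1.41. Across bins, which are not independent replicates, Pearson's r between replicates was 0.915 for Gal4, 0.870 for Sef1, 0.845 for Yrm1 and 0.158 for Lee1.

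**Figure D2:**
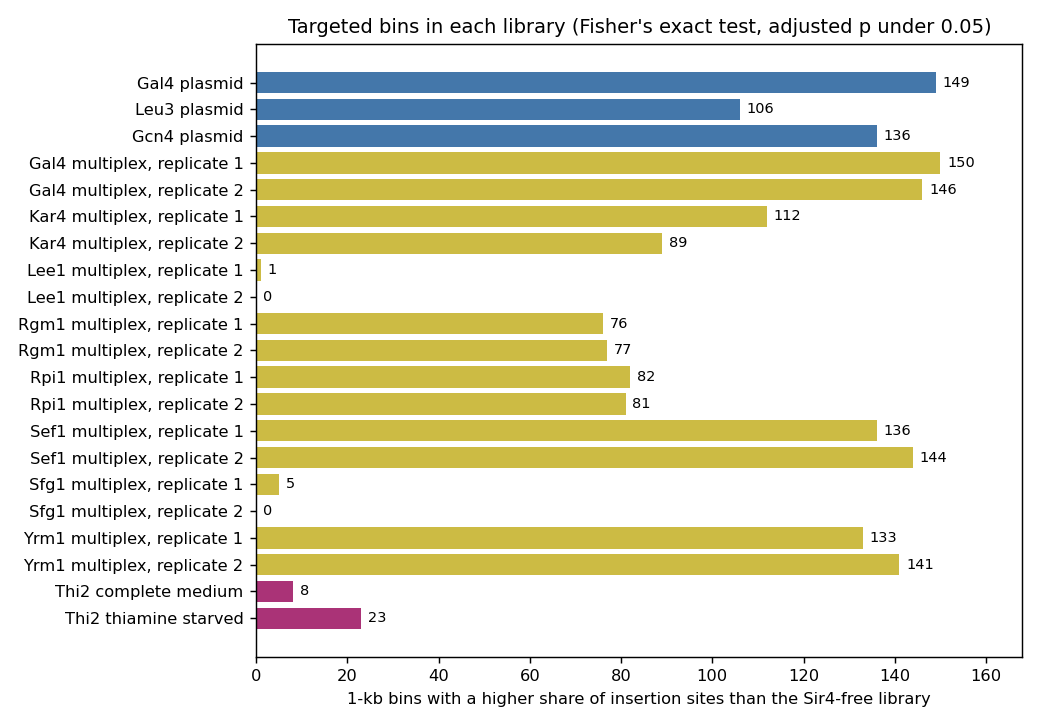
Number of 1-kb bins (horizontal axis) with a higher share of insertion sites than the Sir4-free library, in each plasmid (blue), multiplex (yellow) and Thi2 (purple) library, by Fisher's exact test on single libraries. The counts are 149 for Gal4, 106 for Leu3 and 136 for Gcn4 on plasmids, 0 to 150 in the multiplex libraries, and 8 and 23 for Thi2 in complete and thiamine-free medium.

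Kar4, a regulator of mating and nuclear fusion, marked mating genes. FIG2, an adhesin gene of mating cells (chromosome 3, 267001 to 268000), held 319 and 200 sites, 1.33% ± 0.0709 (SD, n = 2), at log2 8.64 ± 0.26 over the other fusions (adjusted p 2.98e-234), and the Sir4-free library had 1 site there. PRM1, a membrane fusion gene that shares its bin with ERG24, held 1.15% ± 0.171 (log2 5.83 ± 0.20), the cell fusion gene FUS1 0.528% ± 0.0493 (log2 6.91 ± 0.30) and AFR1 0.630% ± 0.114. PCL2 held 1.21% ± 0.287 and RVS161, needed for cell fusion, 0.351% ± 0.0923. The nuclear fusion gene KAR5 held 0.224% ± 0.0358 and the pheromone regulator STE12 0.288% ± 0.00893. Of the mating list 16 of 24 genes were called, as against 4.20% of other genes (adjusted p 1.19e-15; 17 adjusted over the list alone), with FUS2, CIK1, KAR3, PRM2, PRM3, PRM4, AGA1, BAR1, FIG1, SST2 and KAR4 itself among them. Of the 16, PRM3, FIG1, BAR1 and SST2 were not above the Sir4-free library in the same fit (adjusted p 0.260, 0.768, 0.134 and 0.939). FUS3, STE2, GPA1, MFA1, MFA2, ASG7, FAR1 and KAR9 were not called. A bin at the left end of chromosome 3 near GEX1 (1001 to 2000) was raised as well, at 1.30% ± 0.136. Kar4 had 251 bins higher at 167 loci and 46 lower, with 150 higher without replicate 1, 132 by DESeq2 and 166 with at least 5 reads per site. Of the 251, 103 were also above the Sir4-free library in the same fit.

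Rgm1, a zinc-finger repressor, had 1 bin far above its others. The bin at RPI1, a regulator gene (chromosome 9, 138001 to 139000), took 373 and 334 sites, 7.30% ± 0.772 (SD, n = 2) against a mean of 0.0396% in the other fusions (log2 6.59 ± 0.17), and RHO3 in the next bin 1.67% ± 0.187. Other strong bins were those of PGM2 (phosphoglucomutase), UGP1, HXK1, ZNF1 and HXT13. PGM2 held 1.64% ± 0.0602, UGP1 beside AIM26 1.13% ± 0.143, the hexokinase gene HXK1 1.07% ± 0.0285, ZNF1 1.05% ± 0.321 and the transporter HXT13 0.772% ± 0.0514 (log2 7.33 ± 0.43). The stress regulator MSN4 held 0.836% ± 0.0670 and RAS2 1.04% ± 0.0731. Of the hexose transport list 3 of 10 genes were called, HXT13, HXT6 and HXT7, as against 1.84% of other genes (adjusted p 0.00832; 3 adjusted over the list alone). The bins of HXT7 and HXT6 lie close together on chromosome 4 (from 1156001 and 1161001), so these calls need not be independent. Of the filamentous growth list 3 of 12 were called, the regulators MGA1, SOK2 and HMS1 (adjusted p 0.00832; 3 adjusted over the list alone), of which HMS1, on 3 and 7 sites, was not above the Sir4-free library in the same fit (adjusted p 0.476). Rgm1 had 77 bins higher at 64 loci and 49 lower, and 50 higher without replicate 2 and 45 with at least 5 reads per site. Its libraries were the smallest, with 4755 and 4946 sites, so that 0 sites allow a share of up to 0.0631% in replicate 1. Of the 77 higher bins, 59 were also above the Sir4-free library in the same fit. In that fit 12 bins were below the Sir4-free library, and by Fisher's exact test 0 in either replicate.

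Rpi1, a regulator linked to Ras signalling and the cell wall, had its largest share of sites at MIT1, a regulator of filamentous growth (chromosome 5, 141001 to 142000), with 3.86% ± 0.187 (SD, n = 2; log2 4.36 ± 0.14). WSC4, a cell wall sensor that shares its bin with OCA5, held 2.05% ± 0.309 (log2 5.95 ± 0.18), and the glucanosyltransferase gene GAS5, with SIL1, 1.11% ± 0.134 (log2 5.80 ± 0.21). DDR48/PAI3 held 0.824% ± 0.0116 (log2 9.44 ± 0.33), where the Sir4-free library had 1 site. The bins of GCN4 with 0.777% ± 0.0391, VHS1 with 0.729% ± 0.0993 and ICY1 with 0.912% ± 0.0253 followed. The cell wall list did not pass, with 3 of 19 tested genes called (SED1, FKS2 and CCW14; adjusted p 0.187; 3 adjusted over the list alone). List genes on chromosome 11 were outside that test, and there the bins of CWP2/CWP1 (70 and 48 sites; adjusted p 2.84e-17) and PIR1/PIR3 (27 and 25 sites; adjusted p 7.78e-05) were higher. The heat shock list, chosen as a control, was raised, with HSP26, HSP30, SSA1 and SIS1 called out of 14 (adjusted p 0.0282; 4 adjusted over the list alone), on 9 to 21 sites each over both replicates. Against the Sir4-free library in the same fit HSP26 passed (adjusted p 0.0306), while HSP30 (0.280), SSA1 (bin of EFB1, 0.594) and SIS1 (0.0727) did not. Rpi1 had 164 bins higher at 141 loci and 12 lower, 90 higher without replicate 1, and 98 by DESeq2. Of the 164, 81 were also above the Sir4-free library in the same fit.

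Sef1, a zinc-cluster protein, had its fullest bin at KTI12 (chromosome 11, 230001 to 231000), with 3.02% ± 0.232 (SD, n = 2). HAP4, the activator of respiration genes, in the next bin held 1.83% ± 0.0528 (log2 4.83 ± 0.18). COR1, a subunit gene of complex III, held 1.80% ± 0.115 (log2 4.89 ± 0.17), QCR6/PHO4 1.83% ± 0.188, the isocitrate dehydrogenase gene IDH2 (with BAG7) 1.18% ± 0.0300 (log2 5.32 ± 0.19), the aconitase gene ACO1 1.08% ± 0.0815 (log2 5.09 ± 0.20) and ROX1, the repressor of hypoxic genes, 0.774% ± 0.0101. YGR067C, an open reading frame of unknown function, held 2.26% ± 0.159. The iron regulon, a list named for the role of Sef1 homologues, gave 1 of 21 genes, ISU1 with 39 and 33 sites (adjusted p 0.938; 1 adjusted over the list alone), while 6 of 19 cell wall genes were called, among them YGP1, CCW12 and FKS1 (adjusted p 0.00256; 8 adjusted over the list alone). Sef1 had 200 bins higher at 165 loci and 1 lower, with 113 higher by DESeq2, and 88.5% of its higher bins were ones with over 10 Sir4-free sites, as against 38.7% of all tested bins. Of the 200, 143 were also above the Sir4-free library in the same fit.

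Yrm1, a zinc-cluster regulator of drug resistance, marked genes of the multidrug resistance list. AZR1, a drug antiporter gene next to HSV2 (chromosome 7, 942001 to 943000), held 3.78% ± 0.151 (SD, n = 2; log2 6.13 ± 0.16; adjusted p 7.18e-310). The ABC transporter genes YOR1 and SNQ2 held 2.90% ± 0.188 (log2 5.79 ± 0.16) and 0.796% ± 0.116 (log2 4.62), SNG1, a gene of drug tolerance, 1.58% ± 0.130 (log2 5.28 ± 0.18), the lipid transfer gene PDR16 2.13% ± 0.154 (log2 4.56 ± 0.16) and SFK1 2.83% ± 0.273 (log2 5.51 ± 0.16). VHR1 held 2.54% ± 0.205. Of the multidrug list 9 of 18 genes were called, as against 5.15% of other genes (adjusted p 1.22e-06; 10 adjusted over the list alone). These were AZR1, YOR1, SNQ2, SNG1, CIS1, RSB1, QDR2, YPL088W and YLL056C (PDR16, SFK1 and VHR1 are not in the tested list), while PDR5, PDR10, PDR15, FLR1, ATR1, TPO1, PDR3, QDR1 and YRM1 were not. Yrm1 had 219 bins higher at 170 loci and 28 lower, with 138 higher at 5 or more reads per site. Of the 219, 147 were also above the Sir4-free library in the same fit.

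**Figure D3:**
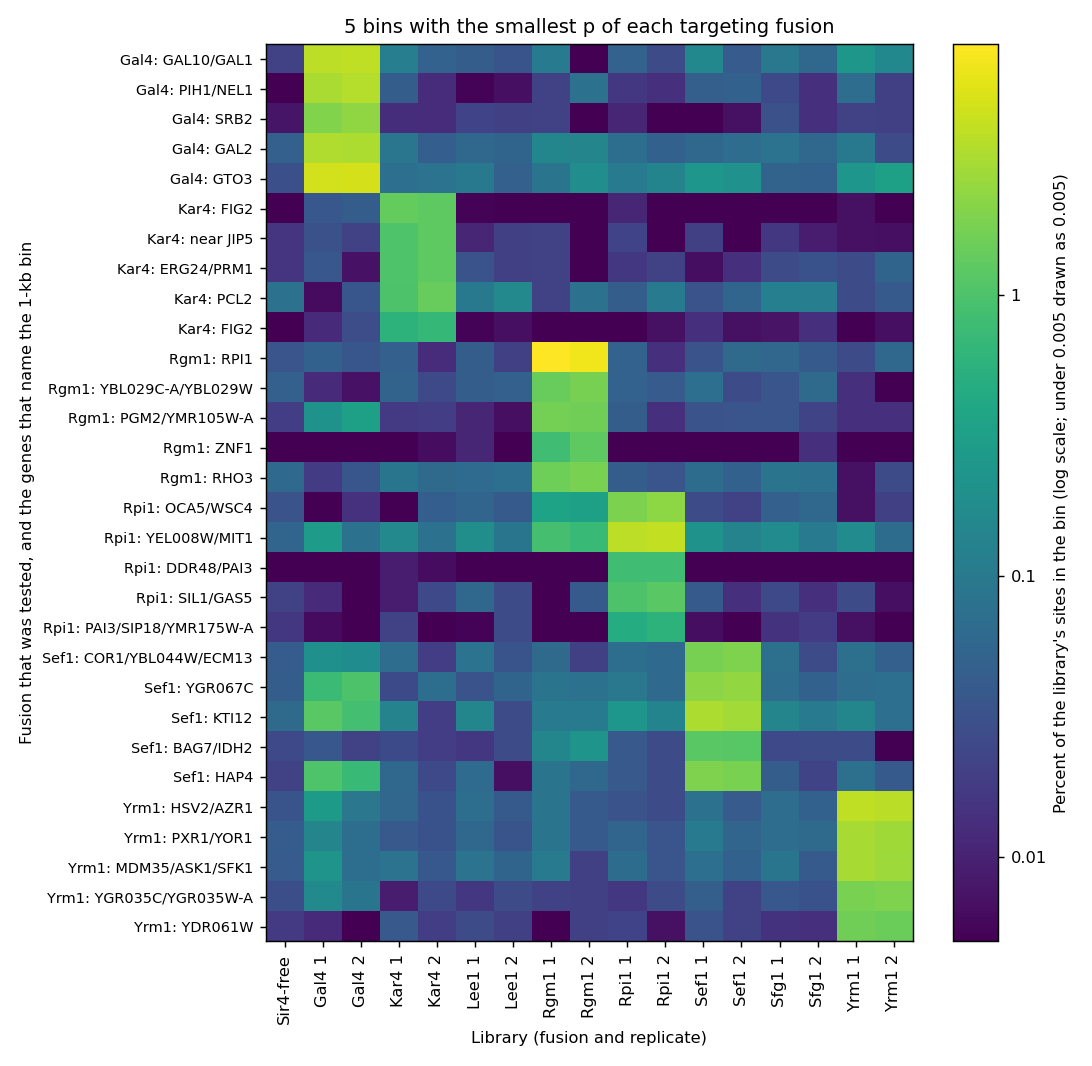
Percent of each library's sites (colour, log scale) in the 5 bins with the smallest p of each of 6 multiplex fusions (vertical axis), in the Sir4-free and the 16 multiplex libraries (horizontal axis). Both replicates of the tested fusion show the raised share, as at RPI1 with 7.30% for Rgm1 or FIG2 with 1.33% for Kar4, and the bin at GTO3 is raised over the Sir4-free library for Gal4, Rpi1, Sef1 and Yrm1.

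Lee1 and Sfg1 showed no bin above untargeted Ty5 when both replicates were fitted together, while single libraries of replicate 1 did. Sfg1, a regulator of filamentous growth, had 469 bins above the mean of the other 7 fusions, but against the Sir4-free library in the same edgeR fit 0 of all 5460 bins were higher (94 of the 5460 at an unadjusted p below 0.05). As alternatives to the 469 above the other fusions, DESeq2 called 17 and the fit with a replicate block 290. AVT1, a vacuolar transporter gene, led with 45 and 19 sites (log2 1.85 ± 0.34) and differed from the Sir4-free share with an adjusted p of 0.989. Lee1, a zinc-finger protein of unknown role, had 29 above the other fusions, and 0 of the 5460 bins were above the Sir4-free library in that edgeR fit (52 of the 5460 at an unadjusted p below 0.05). Against the other fusions DESeq2 called 11, the fit without replicate 1 of Lee1 0, and the fit without its replicate 2 7. ERG26, a sterol gene, led with 12 and 6 sites (adjusted p against the Sir4-free library 0.984), and 79.3% of Lee1's bins were ones with over 10 Sir4-free sites. That share ran from 51.4% for Kar4 to 88.5% for Sef1, with 80.5% for Rpi1, so it does not set Lee1 apart. The filamentous growth list gave 3 of 12 genes for Sfg1 (MSS11, MSB2 and HMS1; adjusted p 0.534), the glycolysis list 6 of 15 (adjusted p 0.0706), and the list of ribosomal protein genes, a control, 2 of 24 for Sfg1 and 0 in the plasmid, Thi2 and other multiplex comparisons. By Fisher's exact test on single libraries, replicate 1 of Sfg1 had 5 bins above the Sir4-free library, at GAL7, GAL10/GAL1, MIT1, VHR1 and KTI12. Replicate 1 of Lee1 had 1, at MIT1, and both replicates 2 had 0. In these replicates 2, 243 (Sfg1) and 198 (Lee1) bins had an unadjusted p below 0.05, higher and lower bins together.

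Most bins were called for 1 fusion, and a few for several. Multiplex fusions were told apart by barcode alone, so calls of several fusions of 1 pool in a bin are not independent. Here a higher bin is one called by Fisher's exact test against the Sir4-free library, and not by the edgeR fit. Multiplex fusions needed the call in both replicates. Leu3, Gcn4 and Thi2 (starved) needed it in their 1 library, and Gal4 in the plasmid library or in both multiplex libraries. Over the 11 fusions compared, 667 bins were higher for at least 1, 523 of them for 1 only. QCR6/PHO4 was shared by 5, namely Gal4, Leu3, Rpi1, Sef1 and Yrm1. GTO3 was shared by Gal4, Rpi1, Sef1 and Yrm1, VHR1 (249001 to 250000) by Gal4, Gcn4, Sef1 and Yrm1, the glucose-6-phosphate dehydrogenase gene ZWF1 by Gal4, Leu3, Sef1 and Yrm1, and SPO24 by Gal4, Gcn4, Sef1 and Yrm1. MRK1/MDH3, MNN4, UTH1 and the bin near PYK2 were shared by 4 as well. Of the fusions' own genes only KAR4 was called in a single-library test, in replicate 2 of Kar4 (24 sites; adjusted p 5.69e-10) and not in replicate 1 (12 sites; adjusted p 0.0555).

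Thi2, the activator of thiamine synthesis, sent Ty5 to thiamine genes in the starved library, and in complete medium no gene of the thiamine list passed the threshold. PDC5, a pyruvate decarboxylase gene induced without thiamine (chromosome 12, 410001 to 411000), took 92 of 9171 sites in the starved library, 1.00% (0.809 to 1.23), against 6 of 27883 in complete medium, 46.6-fold (20.6 to 130; adjusted p 5.62e-45). PDC1 took 57 against 6 (28.9-fold, 12.5 to 82.0; adjusted p 3.80e-25) and THI4, the thiazole synthase gene, 30 against 8 (11.4-fold, 5.11 to 28.8; adjusted p 2.82e-09). At THI74, a putative transporter gene, there were 13 against 0, 13.2-fold more with the 0 set to 3 counts, with 13 against 4 in the neighbouring bin of GPI19. THI20, PHO3, OLA1, YJR151W-A and a bin near GEX1 completed the 10 bins that were higher. None of 2474 was lower, but the small starved library left little power for a lower call. Thinned to the starved library's number of sites, the complete-medium library left a median of 5 (3 to 7 in 20 draws), an alternative chosen after the data were seen.

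Against the Sir4-free library the starved library had 23 higher bins at 21 loci (4.75% of its sites against 0.366%), which were 14 with sites within 3 bp merged and 66 against the plasmid libraries. PDC5 was 72.6-fold higher (38.7 to 150), PDC1 11.8-fold (7.77 to 18.0), THI4 28.9-fold, PHO3, a thiamine-repressed phosphatase gene, 32.5-fold, and THI74 56.4-fold on 13 sites against 2 (12.8 to 515). FCY22, a permease gene, had 9 sites against 0, 26.0-fold with the 0 set to 3 counts. Of the thiamine list 10 of 20 genes were called, as against 0.246% of other genes (adjusted p 7.11e-19; 13 adjusted over the list alone): PDC1, PDC5, THI3, THI4, THI6, THI20, THI21, THI22, THI73 and PHO3. Between the Thi2 libraries it was 5 of 15 (adjusted p 2.31e-09; 10 adjusted over the list alone). In complete medium 0 of 20 were called (1 adjusted over the list alone). Some shares there lay above the Sir4-free share, as at THI6 (0.0359% against 0.00628%) and PHO3 (0.0251% against 0.00503%). At PDC1, THI2, THI7 and THI22 they lay below it. Simulated single-library tests mostly missed 4-fold changes, so the lack of calls does not show that Thi2 was absent from these genes. In that library 8 bins were higher, led by one in the ribosomal DNA near YLR154C-G with 66 sites against 30 (6.28-fold, 4.02 to 10.0) and one near GEX1. A further 7 bins were lower in that library, among them YBL111C with 0 sites against 49 and COS7 with 1 against 47. The 2 bins near GEX1 (chromosome 3, 3001 to 5000), called in both Thi2 libraries, hold or adjoin the site of the native Ty5 element at position 4323, which had 298499 reads in complete medium and 297853 in the starved library against 12221 without Sir4. The 8 complete-medium bins were 2 with sites within 3 bp merged, 4 or 5 with a minimum of reads or shifted bins, and 100 against the plasmid libraries. The Thi2 strain is a haploid with the fusion at the native locus and the control a diploid, so strain and fusion cannot be separated against the Sir4-free library.

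**Figure D4:**
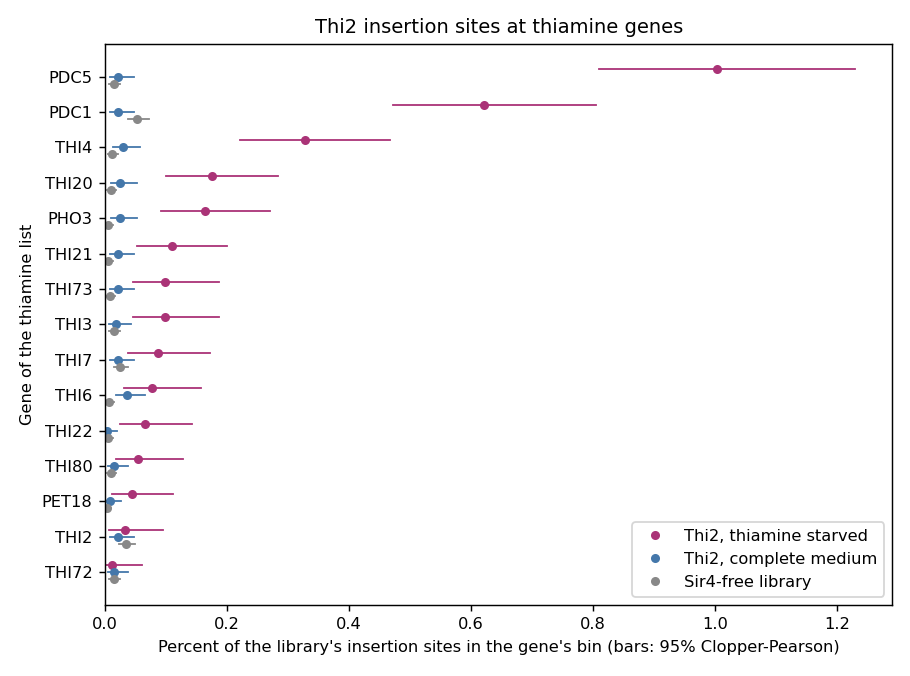
Percent of sites in the bin of each thiamine gene in the starved Thi2, complete-medium Thi2 and Sir4-free libraries, with 95% Clopper-Pearson intervals as bars. PDC5 held 1.00% in the starved library, 0.0215% in complete medium and 0.0138% without Sir4.

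Ty5 is drawn to silent chromatin when Sir4 is present, and the libraries differed in their share of sites near chromosome ends. Within 20 kb of an end lay 6.83% (6.66 to 7.01) of the Sir4-free sites. The share was lower for Gal4, at 1.94% on the plasmid and 1.34% and 0.987% in the multiplex replicates, for Leu3 at 2.39%, Sef1 at 2.84% and 2.43%, Yrm1 at 2.84% and 3.09% and Rpi1 at 3.76% and 4.13%. Smaller gaps were seen for Sfg1 at 5.42% and 6.11% and Thi2 at 5.89% and 5.80%. These depended on the reads asked per site: with at least 5, Thi2 lay above the Sir4-free share, at 5.95% and 6.48% against 5.75%, and replicate 2 of Sfg1 no longer passed, at 5.69%. Gcn4 was higher at 7.76% (adjusted p 3.46e-06), as was replicate 2 of Kar4 at 7.49% (adjusted p 0.00847) but not replicate 1 at 7.04% (adjusted p 0.400), while Lee1 and Rgm1 did not pass within 20 kb. Replicate 2 of Kar4 lost its call within 30 kb (9.68%) and with sites within 3 bp merged (7.17%), and Rgm1 was lower within 10 kb (2.02% and 2.57%) and, in replicate 2, higher within 30 kb (10.9%), against 4.12% and 9.56% without Sir4. Sites in targeted bins count in these shares. With each library's higher bins left out of it and of the control, an alternative chosen after the data were seen, Gal4 held 4.28%, 4.12% and 3.03% and Leu3 3.61%, still lower, while replicate 2 of Kar4 was no longer higher, at 6.57% (adjusted p 0.635), and replicate 1 was lower, at 6.20% (adjusted p 0.00997). The bins of the silent mating loci HML and HMR held 18 Sir4-free sites (0.0226%), and no library passed the threshold there. The lowest adjusted p was 0.0660, for Thi2 in complete medium with 14 sites.

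Barcodes of 1 pool shared slightly more sites than barcodes of different pools. For the 28 pairs of fusions the number of identical sites within pools was a median of 1.11 times that between pools (1.04 to 1.30), and above 1 for 28 pairs in pool 1 and 27 in pool 2. The replicates of Gal4 shared 5468 sites with each other and those of Lee1 411, where Lee1 shared a median of 447 with the other fusions of pool 2.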

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

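Chosen after the result was seen were the tests of Sfg1 targeting in both pools, of reads per site in Sfg1 and Lee1, both tests of the Gal4 and Leu3 plasmid libraries, the tests on sites and on reads of the native Ty5 element, and replicate 2 in the test of read ranks. Of 5 tests the reading was changed after their values were seen, and each place is named below with the reading that the first bound would have given.

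The starved Thi2 library had 10 bins higher than the complete-medium library by Fisher's exact test, which drew attention as a difference between 2 libraries and, with 1 library per medium, tests no difference between media. Sites in stretches at deleted genes drew attention as signal where the Sir4-free library listed none. Each stretch runs between neighbouring Sir4-free sites and is not the gene itself, so its sites need not lie in deleted DNA. In the 4214-bp stretch at SIR4 without a Sir4-free site (chromosome 4, 917495 to 921708), where 33 stretches of the genome are as long, 12 fusion libraries listed 30 sites, 9 from Thi2, 3 from plasmid and 18 from multiplex libraries. In the 6757-bp stretch at LEU2 (chromosome 3, 86155 to 92911), where 5 stretches are as long, there were 4 sites, 3 from the Gcn4 plasmid library and 1 from replicate 2 of Kar4. Reads at the 2 sites of the native Ty5 element, likewise outside the comparisons, reached 18.3% of the library in replicate 2 of Sfg1, with 5.94% in the Sir4-free library and 1.99% as the lowest of the 20 libraries that listed them.

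The 5 bins of Sfg1 and 1 of Lee1 that passed in replicate 1, at GAL7, GAL10/GAL1, MIT1, VHR1 and KTI12, were all led by another fusion of the same pool (611 Gal4 sites against 52 Sfg1 sites at GAL10/GAL1). Reads given to a wrong barcode within the pool may account for them: median reads per site were at most 0.5 times those elsewhere (2 against 4 in Sfg1, 1 against 4 in Lee1), and Sfg1 read numbers ranked with the leader's slightly more in the same pool than in the other (difference of correlations 0.0257, 0.00303 to 0.0489; in replicate 2 0.0195, -0.00561 to 0.0453). Low reads per site are not particular to these bins, since the ratio was 0.56 in the complete-medium Thi2 library, which is outside the pools. Wrong barcodes and true insertions cannot be told apart by identical sites, because 85.9% of the 383 sites were leader sites even in the other pool, so neither the 0 of 6 calls left after their removal (first read as for wrong barcodes) nor the same-pool to other-pool ratio of 0.913 (0.781 to 1.07; first read as against) decides. Greater depth and targeting of Sfg1 itself stay open too, because the bins were picked on replicate 1: thinned to replicate 2, Sfg1 called a median of 2 bins (1 to 4) in place of 5, with none called in 0 of 20 draws (first read as against depth), and its share was 0.633% in replicate 1 and 0.423% in replicate 2 (p 4.02e-04, first read as against targeting in both pools).

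The Gal4 and Leu3 plasmid libraries shared 0 insertion sites, while each shared 406 or 520 with the Gcn4 library. Chance is argued against, since sites 1 bp apart, which occurred 68 and 83 times, give 75.5 shared sites expected. Removal of sites present in both libraries before deposit is consistent with these 0 shared sites and with the 2 native Ty5 sites missing from these 2 libraries alone, but the steps before deposit are not given in the sources used here. Targets common to Gal4 and Leu3 may therefore be understated in these 2 libraries. No biological explanation was tested.

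Kar4 held 1.30% ± 0.136 of its sites in the bin from 1001 to 2000 of chromosome 3, 15.0 times the mean of the other multiplex libraries (0.0869%). Reads of the native Ty5 element misplaced by a few bases are argued against. Of the Kar4 sites in the leftmost 5 bins, 2.39% lay within 10 bp of its 2 sites. Native reads misplaced by more than 10 bp were not tested. A greater number of native reads is argued against too. Kar4 had 11.5 and 12.7 sites per 1000 reads of the native site in this bin (position 1430). The other multiplex libraries had at most 1.23 (3.59 in the Gcn4 plasmid library). A general rise at chromosome ends is argued against as the whole cause, since Kar4 held 1.28 and 1.34 times the mean share of the other fusions at the other 31 ends (highest other library 6.25% of its sites, Kar4 5.07% and 5.31%); the bound of 1.2 set first was not met and would have left this undecided, but it ignored the size of the excess. Targeting by Kar4 near this end is a hypothesis that stays open and was found on the same data. Other technical explanations, such as a repeat shared between chromosome ends, were not tested.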

How the results depend on the processing

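Bins shifted by 500 bp, each Sir4-free listing counted, the thinned complete-medium library, the fit without Sfg1 replicate 1 and leaving out higher bins near chromosome ends were tests chosen after the results were seen. Counts of higher bins stayed within 1.5 times their value for the 3 plasmid libraries under every alternative. The overlap of Gal4 bins kept its result. For each fusion 1 list was followed with at least 2 or 5 reads per site and with merged sites, and it kept its result. For multiplex fusions it was also followed against the Sir4-free library. Other lists that passed, such as cell wall for Sef1 or heat shock for Rpi1, were not followed, and no list was under the remaining alternatives. With at least 2 reads per site Thi2 in complete medium fell from 8 bins to 5 and Lee1 from 29 to 15. With at least 5 reads the bins were 4 for Thi2 in complete medium, 127 for Gal4, 166 for Kar4, 2 for Lee1, 45 for Rgm1, 254 for Sfg1 and 138 for Yrm1. Merging sites within 3 bp left 2 for Thi2 in complete medium and 14 for starved Thi2, and shifted bins left 4 in complete medium. Against the plasmid libraries, the Thi2 libraries had 100 bins (complete) and 66 (starved). With the complete-medium library thinned, a median of 5 bins (3 to 7) were higher between the Thi2 libraries in place of 10, with fewer sites tested. DESeq2 called 132 bins for Kar4, 11 for Lee1, 98 for Rpi1, 113 for Sef1 and 17 for Sfg1. Without TMM, Lee1 had 74. With no minimum, Lee1 had 15 and Sfg1 809. The replicate block gave 290 for Sfg1 and moved no other count by over 1.5 times. Against the Sir4-free library there were 0 for Lee1 and Sfg1, 105 for Kar4 and 88 for Rpi1, and TFC3/NUP60 turned to log2 -0.10 (Lee1) and -0.34 (Sfg1), and the bin near YBL113C to -0.073 (Lee1). Keeping a shared site for 1 barcode gave 13 for Lee1 and 818 for Sfg1. Leaving out either replicate of the fusion itself, or replicate 1 of Sfg1, gave 150 to 233 for Kar4, 0 to 21 for Lee1, 50 to 77 for Rgm1, 90 to 152 for Rpi1 and 13 to 167 for Sfg1, the lone library being assumed to vary like the others. Of the values of single named bins 1609 kept direction and call, 197 lost the call and 3 reversed.

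Near chromosome ends, the Sir4-free share was 4.12% within 10 kb, 9.56% within 30 kb, 6.27% with at least 2 reads and 5.75% with at least 5. With at least 5 reads the Thi2 libraries turned above it, at 5.95% (complete) and 6.48% (starved), as did the starved library with at least 2 reads at 6.37%, while complete medium with at least 2 lost its call at 5.93%. With each library's higher bins left out, Kar4 replicate 1 fell below the control at 6.20% and replicate 2 turned, without a call, to 6.57%. Calls also changed for Kar4 replicate 1 (4.88% within 10 kb, 6.42% with at least 5 reads), Kar4 replicate 2 (9.68% within 30 kb, 7.17% merged), Rgm1 (2.02% and 2.57% within 10 kb, 10.9% within 30 kb in replicate 2) and Sfg1 replicate 2 (3.78% within 10 kb, 5.77% and 5.69% with at least 2 and 5 reads). Except where a cause is given above, the cause was not tested. Motif enrichment and its alternatives, promoter regions and promoter regions extended by 200 bp were not run. Depth limits Rgm1 most, and 4-fold changes were mostly missed in simulated single-library tests.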

Other observations

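The test of Rgm1 at other regulators' genes was chosen after the result was seen.

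Further bins that the naming rule lists lay at genes of little known function or beside genes outside the fixed lists. For Yrm1, YGR035C held 1.85% ± 0.0676 of the sites (SD, n = 2; log2 6.12 ± 0.19), YMR103C 2.36% ± 0.0632 (log2 4.39 ± 0.17), and the bin of GIP3 and ISU1, a gene of iron-sulfur cluster assembly, 0.964% ± 0.201 (log2 4.77 ± 0.20). For Sef1, a bin near PDR12, the weak-acid transporter gene, held 1.13% ± 0.0216 (log2 4.33 ± 0.18). For Kar4, a bin near YIL014C-A held 0.520% ± 0.0112 (log2 6.38 ± 0.29).

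At other marker genes of the strains, in stretches without a Sir4-free site, fusion libraries listed 33 sites in the 1197-bp stretch at URA3, 41 in the 733-bp stretch at TRP1, 11 in 213 bp at HIS3, 6 in 3259 bp at LYS2 and 3 in 1226 bp at MET15. Stretches as long without a Sir4-free site were common in the genome (1327, 3805, 15326, 60 and 1249 in that order), so these sites need not lie in deleted DNA.

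Repeated insertion at the same base in strongly targeted bins is a hypothesis under which counts of distinct sites would understate folds. Its test asked for over 1.5 times as many reads per site in higher bins as elsewhere in each plasmid library. The ratio of medians was 5.25 for Gal4, 2.80 for Leu3 and 1.86 for Gcn4, so folds at the strongest bins may be understated. It was 6.05 in the starved Thi2 library but 0.56 in complete medium. In the multiplex replicates it was 2.67 and 2.5 for Gal4, 2.25 and 1.67 for Sef1, 2.25 and 2 for Yrm1 and 1.8 and 1.67 for Rpi1. It was 1.5 and 1.33 for Rgm1 and 1.25 and 1.33 for Kar4. In replicate 1 of Sfg1 it was 0.5 and in that of Lee1 0.25. The pattern thus held for most targeting fusions but was not general. Other sources of unequal reads per site, such as fragment length, were not tested.

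That Rgm1 insertions gather at the genes of the other regulators in the pools was a hypothesis drawn from the RPI1 bin with its 707 sites. Of the 7 genes Rgm1 was higher at 1, RPI1 itself, with at most 2 sites over both replicates at each of the others, which argues against it.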
